A study of Mus musculus with 16 samples.

How the data were processed

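RNA was measured in alveolar macrophages from mouse lungs with Affymetrix expression arrays. Per the labels' protocols, perfused lungs were digested with collagenase and DNase, red blood cells were lysed, and cells positive for both CD11c and SiglecF were sorted. RNA was extracted with a micro-scale column kit and labelled with biotin. The labels also give the tissue as whole lung homogenate, while the cell type field and the sorting protocol name alveolar macrophages. The sorted cells were taken as the material here.

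The deposited log2 values were produced with RMA, per the submitters' processing notes, which name the affy package version 1.36.1 and R version 2.15.1. RMA corrects the background, normalizes the arrays by quantiles and summarizes each probe set. That the deposited values are on the log2 scale was taken from their range, from -0.05 to 12.7, and from the scale RMA gives. The genome build was not given in the sources used here, and no coordinates are reported. The value table held 25206 probe sets on 16 arrays, with 1 probe set per Entrez gene. Names came from the platform annotation. Of the probe sets, 23185 had 1 gene symbol, 2021 had none and 0 had several. All 23185 Entrez identifiers with a symbol were found in the RefSeq gene table, and 0 symbols needed updating. The number of arrays limits the precision of every value.

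The 16 arrays formed 4 groups of 4 by infection history and current infection, as the labels describe each animal. Naive Control and Naive SP3 mice had received saline earlier. Experienced Control and Experienced SP3 mice had received 2 infections with pneumococcus serotype 19F. SP3 marks mice 4 hours into infection with pneumococcus serotype 3, and Control marks mice at rest. The columns of per-sample values not used numbered 0.

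A group-means model was fitted to all 16 arrays and all 25206 probe sets with limma 3.58.1 in R 4.3.3, without a filter or a covariate. The 4 groups shared 1 estimate of the spread with 12 residual degrees of freedom. Empirical Bayes moderation added 4.59 prior degrees of freedom, for a total of 16.6. The study design implied 5 contrasts. They were Experienced minus Naive at rest, Experienced minus Naive during infection, SP3 minus Control in Naive mice, SP3 minus Control in Experienced mice, and the difference between these SP3 responses, called the interaction. P-values were adjusted by the Benjamini-Hochberg method over all probe sets within a contrast. A gene was called at an adjusted p below 0.05. Every p-value is two-sided, and every adjusted p for a gene comes from limma. Fold changes are differences of group means on the log2 scale with their standard errors (SE).

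A total of 29 gene lists, 16 for pathways and 13 for cell types, was tested in the same model with fry, limma's rotation test, with Benjamini-Hochberg adjustment over the 29 lists within a contrast. The p-value of fry tests whether the genes of a list move, on balance, one way. Its mixed p-value tests whether they change in either direction, and neither compares a list with other genes. The camera test with a preset correlation of 0.01 and with an estimated correlation served as alternatives. Members were also counted past the threshold over all genes and adjusted over the list alone. Overlaps of calls were set beside the number expected for independent lists. Correlations of fold changes were computed across genes, which are not independent replicates.

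Named genes were chosen by a rule. Among called genes whose compared groups did not overlap on any array, the rule took the 10 largest changes up and the 10 largest down per contrast. Where no gene was called it took the 10 smallest p-values. It added Itgax and Siglecf, which encode the sort markers, H2-Ab1, Cd74, and up to 4 members of smallest p in each list described. Probe sets without a single symbol, predicted or unnamed loci, microRNAs, small nuclear and nucleolar RNAs and pseudogenes were left out of the largest changes. Genes outside the rule are said to have been chosen after their values were seen. The contrasts, the tests, the gene lists, the naming rule and the alternatives were fixed before the data were examined, except where the text says that a test came later.

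The calculations were tested on simulated arrays in which 100 genes at each fold size were changed. The changed genes were drawn from probe sets whose mean lay above the median of all deposited values, and noise was independent between genes. Dimmer genes and deviations of whole arrays were thus not covered. For the contrast of experience at rest, 76% of the 2-fold and 98% of the 4-fold changes among 25206 genes were recovered. For SP3 in Naive mice the shares were 79% and 98%, and for the interaction 32% and 87%.

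The alternatives were a filter keeping the 13480 probe sets above the median of all deposited values on at least 4 arrays, quantile normalization, centring of array medians, the replicate number as a block, a fit of the compared groups alone, empirical Bayes with an intensity trend and robust hyperparameters, array quality weights, and leaving out each of the 16 arrays in turn. Other groupings of the same arrays were refitted, all 35 for a comparison of 4 with 4 arrays and 100 drawn at random with a fixed seed for the interaction. Scanner files and scan dates were not among the sources, so neither the background signal per probe nor a scan batch was assessed.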

Results

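Gene expression was measured on 16 arrays, 1 per mouse, in alveolar macrophages sorted from lungs. The study asked whether recovery from pneumococcal pneumonia changes these cells and their answer to a new infection. Naive mice had received saline and Experienced mice 2 infections with pneumococcus serotype 19F, more than a month earlier. Each history had 4 mice at rest (Control) and 4 mice 4 hours into infection with serotype 3 (SP3). Values are RMA expression on the log2 scale, and the number of arrays limits their precision. A level below the median of all values, 2.62, is not shown to lie above the background, which is not known, so the size of a difference from it is not exact. Of the genes named below, this holds in at least 1 group for Serpina3f, Ighg2b, Igkv4-80, Hamp, Il23a, Ifnb1, Oas1g, Ear6, Erc2, Frk, Scel, Tek, Vcan, Mkx, Catspere1 and Mzb1. Array medians lay between 2.49 and 2.82, and arrays of a group correlated across genes at 0.978 to 0.991, apart from Experienced Control 3. That array had a mean correlation of 0.962 with its group, an SD of 2.00 against 2.22 to 2.24 in its group, and the lowest quality weight, 0.150. The first 3 principal components held 28.6%, 17.9% and 11.6% of the variance.

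Transcripts of both sort markers were measured first. Itgax, which encodes CD11c, differed by 0.23 between Experienced and Naive mice at rest (adjusted p 0.771). Siglecf had a log2 fold change of -0.76 at rest (SE 0.18, adjusted p 0.0888) and of -0.49 during infection (adjusted p 0.523). Neither passed in any of the 5 contrasts, and neither did H2-Ab1 or Cd74, which serve antigen presentation.

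The comparison of Experienced with Naive mice at rest asked what past pneumonia leaves in resting macrophages. Lepr, which encodes the leptin receptor, averaged 7.40 ± 0.20 (SD, n = 4) in Naive Control and 3.47 ± 0.63 in Experienced Control, a log2 fold change of -3.93 (SE 0.28, adjusted p 4.54e-07). Pdk4, a kinase that restrains pyruvate dehydrogenase, fell by 3.08 (SE 0.20, adjusted p 1.85e-07). Marco, a scavenger receptor of alveolar macrophages, averaged 9.06 ± 0.38 in Naive Control and 6.35 ± 0.59 in Experienced Control, a 6.58-fold lower level (adjusted p 0.00465). Msr1, another scavenger receptor, moved the other way and rose by 1.51 (SE 0.26, adjusted p 0.0073), and the adaptor gene Sash1 rose by 1.93 (SE 0.14, adjusted p 8.84e-07).

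Experience at rest went with 161 called genes, 110 of them lower in Experienced mice and 51 higher. Changes of at least 2-fold made up 79 of the former and 29 of the latter. Unadjusted p-values lay below 0.05 for 1651 genes, or 6.55%. Besides those above, the largest decreases were those of Vstm2a (-3.59), Adgrl3 (-3.32), Sema3e (-3.28), Lipf (-3.05), Erc2 (-2.77), Trp53i11 (-2.57) and Wwtr1 (-2.48), with adjusted p-values from 4.73e-08 to 0.000255. The largest increases outside the immunoglobulin genes were those of Sash1, Apbb2 (1.67), Tns3 (1.57), Msr1, Gng12 (1.47) and Cd93 (1.39). Leaving out Naive Control 4 lowered the number of called genes to 106, 33 higher and 73 lower. The higher genes numbered 29 without Experienced Control 2 and 94, beside 111 lower ones, without Experienced Control 3. Leaving out Experienced Control 3 thus moved the share of higher genes from 31.7% to 45.9%. Without any other single array that share was 26.9% to 34.0%, so the balance of the directions depended mainly on Experienced Control 3. Array weights called 159 higher and 199 lower genes, and the compared groups alone 28 and 68. Another grouping of the same 8 arrays, with Experienced Control 3 in the place of Naive Control 3, called 801 genes.

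Immunoglobulin transcripts gave 4 of the 10 largest increases. Igha, the constant region of IgA, averaged 4.12 ± 2.08 in Naive Control and 8.73 ± 1.56 in Experienced Control, a log2 fold change of 4.61 (SE 0.89, adjusted p 0.0195). Its adjusted p rose to 0.0839, 0.0836, 0.0781 and 0.0555 without Naive Control 2, Naive Control 4, Experienced Control 2 and Experienced Control 3, in a range from 0.00119 to 0.161 over all alternatives. Ighg2b rose by 3.90 (SE 0.62, adjusted p 0.00305) and the light chain gene Igkv4-80 by 1.78 (SE 0.19, adjusted p 6.06e-05), from dim Naive Control means of 1.59 and 2.13 that leave these sizes inexact. Ighj3 passed narrowly (adjusted p 0.0472) and missed the threshold without 12 of the 16 arrays. Its adjusted p was 0.109, 0.111 and 0.123 without Naive Control 1, 3 and 4, and 0.182 and 0.118 without Experienced Control 2 and 3. Without Naive SP3 1 to 4 in turn it was 0.0565, 0.0642, 0.0684 and 0.0693, and without Experienced SP3 1 to 3 it was 0.0588, 0.0690 and 0.0673, in a range of 0.0170 to 0.291 over all alternatives. The B cell list, 10 measured genes, had 0 called members at rest (median -0.61, adjusted p 0.82).

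**Figure D1:**
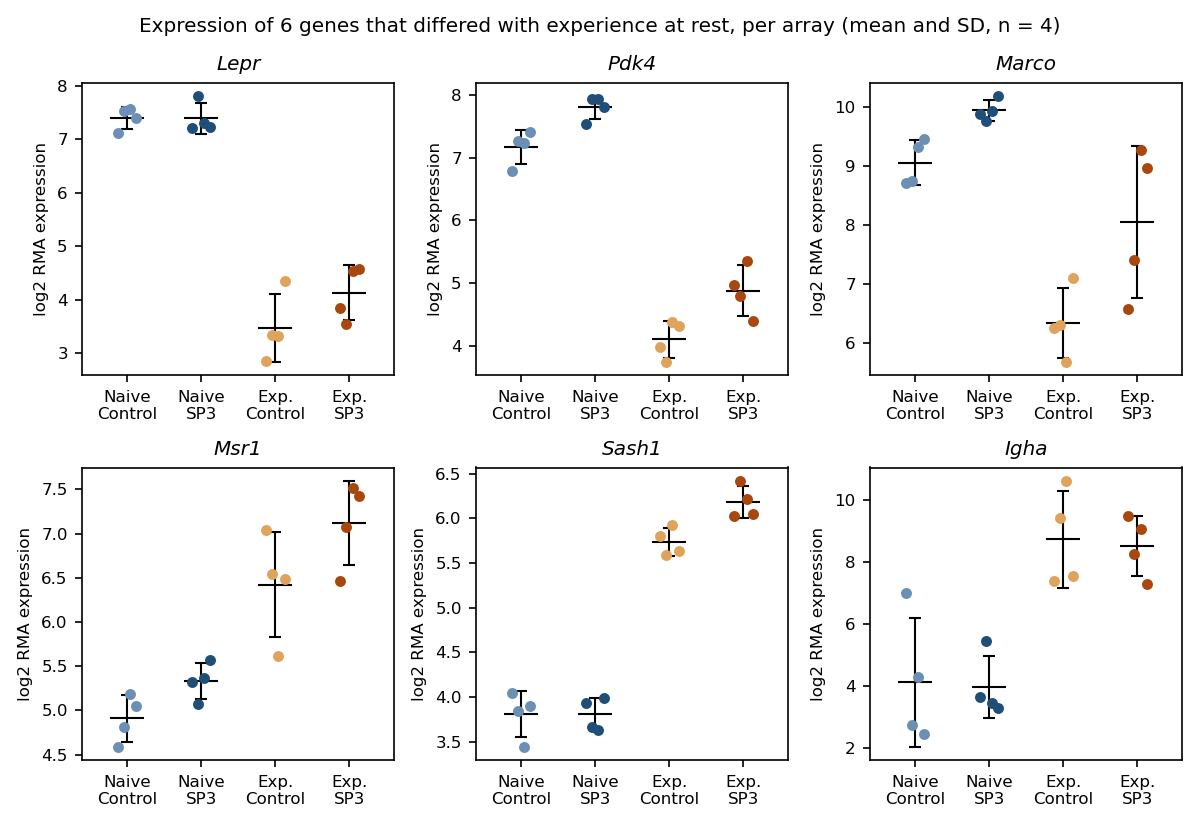
Log2 RMA expression (vertical axis) of Lepr, Pdk4, Marco, Msr1, Sash1 and Igha in the 4 groups (horizontal axis), with a dot per array, a line at the mean and bars of 1 SD, n = 4. Lepr averaged 7.40 in Naive Control and 3.47 in Experienced Control, and Igha 4.12 and 8.73.

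Receptors for uptake of particles changed in both directions at rest. Among 24 measured scavenger, Fc and complement receptors, Msr1 rose and 4 fell, among them Marco, Colec12 (-1.66) and Cd36 (-1.36), and the same numbers passed when adjusted over the list alone. The list had no net direction (adjusted p 0.808), while its mixed test passed (adjusted p 1.21e-05). Of 28 measured genes of resident alveolar macrophages, 0 rose and 4 fell, or 9 when adjusted over the list alone, with Marco and Krt19 (-1.39, SE 0.23) among them. That list missed (median -0.09, adjusted p 0.746). Of its 4 fallen genes only 2 passed without Naive Control 3, Naive Control 4, Experienced Control 1 or Experienced Control 2. Of 29 inflammatory cytokines and chemokines, 1 rose and 2 fell, or 2 and 6 adjusted over the list alone. Tnf fell by 1.28 (SE 0.20, adjusted p 0.00267). Tlr5, the flagellin receptor, fell by 1.76 (SE 0.33, adjusted p 0.0148) as the only one of 29 pattern recognition genes to pass. Without Naive Control 3, Naive Control 4, Experienced Control 1 and Experienced Control 2 its adjusted p was 0.0516, 0.0502, 0.0600 and 0.0558, in a range of 0.00188 to 0.0600 over all alternatives. Epcam, an epithelial adhesion gene, fell by 1.97 (SE 0.23, adjusted p 0.000178) in the epithelium list of 20, whose median was -0.52 (adjusted p 0.746). Ms4a7 of the 19 monocyte-derived macrophage genes rose by 0.92 (SE 0.15, adjusted p 0.00515).

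The other cytokine calls at rest, those of Osm and Ccl22, were lost when any of several arrays of either group was left out. Osm rose by 1.00 (SE 0.20, adjusted p 0.0237), and its adjusted p became 0.0619, 0.0771, 0.0883, 0.0981 and 0.0778 without Naive Control 3, Naive Control 4, Experienced Control 1, Experienced Control 2 and Experienced Control 4, in a range of 0.00023 to 0.193. Ccl22 fell by 1.57 (SE 0.30, adjusted p 0.0203), and its adjusted p became 0.0658, 0.0778, 0.0543, 0.0927 and 0.0705 without Naive Control 1, Naive Control 2, Naive Control 4, Experienced Control 1 and Experienced Control 2, in a range of 0.00204 to 0.0927. Without Experienced Control 3, 2 genes of the list rose, and without Naive Control 3, 3 fell.

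No list passed by fry at rest, 0 of 29. The mixed test called 6 lists, camera called 7 with the preset correlation and 0 with an estimated correlation. The 29 cell division genes came nearest, 28 of them lower in Experienced mice (median -0.32, fry p 0.00245, adjusted p 0.071, adjusted p = 0.188 with an estimated correlation), with 0 members called and 3 adjusted over the list alone. Members called numbered 0 in the remaining lists. These were MHC class II (adjusted p 0.959), type I interferon-stimulated genes (0.991), interferon-gamma-inducible genes (0.808), NF-kB regulators (0.746), glycolysis (0.746), oxidative phosphorylation (0.988), the tricarboxylic acid cycle (0.988), fatty acid oxidation (0.959), cholesterol synthesis (0.82), immediate-early and heat-shock genes (0.808), hypoxia (0.82) and alternative activation (0.746). The cell type lists among them were monocytes (0.746), neutrophils (0.82), eosinophils (0.82), dendritic cells (0.746), T cells (0.959), NK cells (0.746), endothelium (0.746), fibroblasts (0.82) and red blood cells (0.808). Median and mean differed in sign in 5 lists, pattern recognition, oxidative phosphorylation, the tricarboxylic acid cycle, eosinophils and monocyte-derived macrophages. The type I interferon list had a negative median and mean beside a positive test direction. Adjusted over the list alone, 1 member rose in each of the interferon-gamma, NF-kB, glycolysis, monocyte and T cell lists, and 2 alternative activation genes and 1 gene each of monocytes, neutrophils and eosinophils fell.

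The comparison during infection asked how macrophages of Experienced and Naive mice differ 4 hours after the new pneumococcus. Serpina3f, a serine protease inhibitor, averaged 1.37 ± 0.14 in Naive SP3 and 5.94 ± 1.25 in Experienced SP3, a log2 fold change of 4.57 (SE 0.41, n = 4, adjusted p 1.16e-05) whose size is not exact at so dim a Naive level. The cytokine genes Il17a and Il17f rose by 2.92 (SE 0.33, adjusted p 0.000109) and 3.15 (SE 0.31, adjusted p 3.55e-05). The chemokine gene Cxcl9 averaged 4.27 ± 0.36 in Naive SP3 and 7.01 ± 1.15 in Experienced SP3 (adjusted p 0.00176). Ctla4, better known from T cells, rose by 2.25 (SE 0.38, adjusted p 0.00598). Among 12 measured T cell genes 0 were called and 2 passed adjusted over the list alone (median 0.19, adjusted p 0.841).

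Between Experienced and Naive mice during infection 162 genes were called, 81 in each direction. At least 2-fold were 50 of the higher and 49 of the lower ones. Unadjusted p-values lay below 0.05 for 1686 genes, or 6.69%. Called genes numbered 100, 98 and 100 without Naive SP3 3, Experienced SP3 2 and Experienced SP3 4, and 322 with array weights, 172 higher and 150 lower. Higher genes came to 50, 45, 46, 53 and 47 without Naive SP3 2, Naive SP3 3, Experienced SP3 2, Experienced SP3 3 and Experienced SP3 4, and lower genes to 52 and 53 without Experienced SP3 2 and Experienced SP3 4. The largest increases also held Fmnl2 (2.92), Oas1g (2.77), Ifi47 (2.63) and Sash1 (2.38). Lepr (-3.26), Tcim (-3.06), Adgrl3 (-3.06), Pdk4 (-2.93), Wwtr1 (-2.90), Sema3e (-2.86), Lipf (-2.84), Vstm2a (-2.81), Frk (-2.59) and Erc2 (-2.25) had the largest decreases, with adjusted p-values from 1.24e-07 to 0.000584. Igha differed by 4.57 (adjusted p 0.0224), which became 0.0638, 0.0925, 0.0790, 0.0591, 0.0635 and 0.0721 without Naive SP3 1, Naive SP3 3, Naive SP3 4, Experienced SP3 1, Experienced SP3 2 and Experienced SP3 3, in a range of 0.00314 to 0.0925.

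The interferon-gamma-inducible list passed between infected groups and the type I interferon list missed. Of 22 measured interferon-gamma-inducible genes, 21 had a positive fold change and 3 rose, among them Cxcl9 and Gbp3 (1.81, SE 0.29, adjusted p 0.00342), or 13 adjusted over the list alone. Their median was 0.67, and this was the only list to pass by fry (adjusted p 0.0331, adjusted p = 0.081 with an estimated correlation). The call was lost without Naive Control 4 (adjusted p 0.0525), Naive SP3 2 (0.139), Naive SP3 3 (0.115), Naive SP3 4 (0.0569), Experienced Control 1 (0.0524), Experienced Control 4 (0.0543), Experienced SP3 2 (0.0722), Experienced SP3 3 (0.110) and Experienced SP3 4 (0.149), in a range of 1.96e-20 to 0.242 over all alternatives. The replicate block and the fit of the compared groups alone ended it as well. All 25 measured type I interferon-stimulated genes had a positive fold change, with a median of 0.92, and 4 rose, or 18 adjusted over the list alone, with a missed test (adjusted p 0.0935). Without Naive SP3 1, 2 or 3 or Experienced SP3 2, 3 or 4 the members called fell to 0, and without Experienced SP3 1 there were 16. Leaving it out also raised the interferon-gamma count, to 9. Experienced SP3 1 itself showed no such difference, with a type I list mean of 4.13 against 3.89 to 4.61 in Naive SP3 and 5.40 to 5.58 in the other Experienced SP3 arrays. Its interferon-gamma list mean was 4.77, against 4.38 to 4.75 and 5.36 to 5.94.

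In the remaining lists few genes differed during infection. Osm, a cytokine of the interleukin-6 family, rose by 1.24 (SE 0.20, adjusted p 0.00375) alone among the 29 cytokines and chemokines (adjusted p 0.841). Msr1 rose by 1.79 (SE 0.26) and Colec12 fell by 1.86 (SE 0.25) among the 24 uptake receptors (adjusted p 0.988), while Marco missed (-1.89, adjusted p 0.0831). Tlr5 fell by 1.55 (SE 0.33, adjusted p 0.0375) alone among the 29 pattern recognition genes, and missed without 10 of the arrays. Its adjusted p was 0.0556 and 0.0566 without Naive Control 1 and 4, 0.0524 and 0.0549 without Experienced Control 1 and 2, and 0.0786, 0.113 and 0.101 without Naive SP3 1, 2 and 3. Without Experienced SP3 2, 3 and 4 it was 0.157, 0.112 and 0.163, in a range of 0.00283 to 0.178. Epcam fell by 1.27 (SE 0.23, adjusted p 0.012), with an adjusted p of 0.0523 without Experienced SP3 2 in a range of 0.00381 to 0.0523. In the alveolar macrophage, neutrophil and dendritic cell lists 1 member each rose, Fabp5, Csf3r and Ffar2, and in the eosinophil list Ear6 fell. These calls were all lost without Experienced SP3 2 (adjusted p 0.118, 0.0962, 0.0963 and 0.122), and over all alternatives their adjusted p reached at most 0.155, 0.115, 0.119 and 0.122 and at least 0.00199, 0.0127, 0.00091 and 0.00389. Each of the other 7 infected arrays ended at least 1 of them, and Experienced Control 2 and Experienced Control 4 ended that of Fabp5. The remaining 19 lists had 0 called members (adjusted p 0.841 to 0.988). Adjusted over the list alone, 2 uptake receptors rose and 4 fell, and 2 cytokines rose and 1 fell. Median, mean and test differed in sign for 7 lists, those of pattern recognition, uptake receptors, alternative activation, monocytes, B cells, NK cells and epithelium. Of the 11 counts of called list members above 0 during infection, 10 moved by more than 1.5 times without some array, and 4 of 8 did so at rest. None of the counts that moved was above 5.

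The SP3 response of Naive mice showed what serotype 3 does to macrophages without that history. Cxcl1, a chemokine that draws neutrophils, rose from 4.60 ± 0.14 in Naive Control to 8.26 ± 0.11 in Naive SP3, a log2 fold change of 3.66 (SE 0.12, n = 4, adjusted p 2.5e-11). Hamp, which encodes the iron hormone hepcidin, rose by 5.42 (SE 0.57, adjusted p 1.82e-05). Il23a, a subunit of interleukin-23, rose by 4.87 (SE 0.32, adjusted p 2.12e-07). Both averaged below the median of all values in Naive Control (2.17 and 2.21), so neither size is exact. Acod1, the enzyme that makes itaconate, rose by 3.47 (SE 0.42, adjusted p 6.64e-05) and Tnf by 2.87 (SE 0.20, adjusted p 2.82e-07). Glp1r, the receptor of glucagon-like peptide, fell by 1.83 (SE 0.36, adjusted p 0.00417) and Tlr5 by 1.77 (SE 0.33, adjusted p 0.00263).

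Infection of Naive mice changed 1964 genes, of which 769 rose and 1195 fell, 290 and 240 of them at least 2-fold. Unadjusted p-values lay below 0.05 for 4944 genes, or 19.6%. Leaving out Naive SP3 3 gave 1209 called genes, 506 risen and 703 fallen, and leaving out Experienced Control 3 gave 2974, 1268 of them risen. Array weights gave 1218 risen genes. Cxcl3 (4.79), Cxcl10 (3.64), Ccl4 (3.38), Htra4 (3.31), Slc7a11 (3.21) and Ereg (3.16) completed the 10 largest increases. Decreases were smaller, the largest being those of Scel (-2.20), Gbp8, Arrdc3 (-1.98), Dna2 (-1.87), Tmem273 (-1.84), Glp1r, Nol4l (-1.82), Tlr5, Ucp3 (-1.73) and Fosb (-1.72).

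NF-kB regulators formed the most uniform group in Naive mice. Of 20 measured genes 18 rose and 0 fell, or 20 adjusted over the list alone, with a median of 1.38 (adjusted p 2.09e-08, adjusted p = 0.000923 with an estimated correlation). Tnip1 rose by 2.16 (SE 0.15), Bcl3 by 1.95 (SE 0.15) and Tnfaip3 by 1.57 (SE 0.14). Of 29 cytokines and chemokines 15 rose and 0 fell, or 18 adjusted over the list alone, with Cxcl1, Il23a, Tnf and Cxcl2 (2.18) among them (median 1.16, adjusted p 1.98e-06, adjusted p = 0.026 with an estimated correlation). The endothelium list was the only one called downward, with Tek (-1.47, SE 0.28) and Kdr (-1.43) among 4 of its 12 genes, or 8 adjusted over the list alone. Its median was -0.74 (adjusted p 0.0449, adjusted p = 0.493 with an estimated correlation). That call was lost without 12 of the arrays. Its adjusted p was 0.0866 and 0.0622 without Naive Control 1 and 4, 0.0887, 0.142 and 0.114 without Naive SP3 2, 3 and 4, and 0.0613, 0.0612 and 0.0623 without Experienced Control 1, 2 and 4. Without Experienced SP3 1 to 4 in turn it was 0.0606, 0.0563, 0.0518 and 0.0646, in a range of 8.96e-07 to 0.493 over all alternatives. Camera called 7 lists with the preset correlation and 2 with an estimated correlation, and the mixed test called 16.

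Interferon genes moved little as a group in Naive mice. Of the 25 type I interferon-stimulated genes 4 rose, or 5 adjusted over the list alone, among them Ifit1 (3.02, SE 0.48, adjusted p 0.000782), with a median of 0.02 (adjusted p 0.676). Without Naive SP3 4 only 1 rose and without Experienced SP3 1 there were 7. Of the 22 interferon-gamma-inducible genes 5 rose, among them Cxcl10, Irf1 (1.31) and Gbp5 (2.24), or 5 up and 2 down adjusted over the list alone (median 0.06, adjusted p 0.629). Pattern recognition genes went both ways, with 8 risen and 3 fallen of 29, or 11 and 6 adjusted over the list alone (adjusted p 0.174), Clec4e (2.42, SE 0.30) and Nlrp3 (1.27) among the former. The alveolar macrophage list had 5 risen and 4 fallen genes of 28, or 7 and 6 adjusted over the list alone (adjusted p 0.84). Kcnn3 fell by 1.45 (SE 0.12, adjusted p 9.76e-07), Slc7a2 rose by 1.18 and Krt19 fell by 1.29. The median and mean of that list were positive beside a negative test direction.

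Metabolic genes changed singly in Naive mice. The hexokinase gene Hk2 rose by 1.76 (SE 0.15, adjusted p 1.94e-06) and the glucose transporter gene Slc2a1 by 0.87 among 3 risen of 16 glycolysis genes, or 3 up and 1 down adjusted over the list alone (adjusted p 0.396). Eci2 rose by 1.08 and Cpt1a fell by 0.76 among 23 fatty acid oxidation genes (adjusted p 0.76). Of 24 tricarboxylic acid cycle genes 1 fell, or 0 adjusted over the list alone (adjusted p 0.865), of 48 oxidative phosphorylation genes 0 changed (adjusted p 0.676), and of 16 hypoxia genes 2 rose, or 3 up and 1 down adjusted over the list alone (adjusted p 0.676). Immediate-early and heat-shock genes split into 3 risen and 3 fallen of 24, Fosl1 (1.27) and Klf4 (-0.90) among them, or 3 and 6 adjusted over the list alone (adjusted p 0.656). Ccl17 rose by 2.47 (SE 0.46) alone in the alternative activation list of 16 (adjusted p 0.836), and Ear6 rose by 2.83 (SE 0.46) alone among 9 eosinophil genes (adjusted p 0.0855). Members that fell were 2 dendritic cell genes, Tlr3 (-1.19) and Wdfy4 (-0.74), 2 neutrophil genes, the monocyte gene Ace (-0.86), 1 NK cell gene and 1 cell division gene. The uptake receptors had 1 risen and 2 fallen genes, or 2 and 4 adjusted over the list alone (adjusted p 0.676). No member was called in the lists of MHC class II (adjusted p 0.656), cholesterol synthesis, monocyte-derived macrophages, T cells and fibroblasts (0.676 for all 4), B cells (0.396), epithelium (0.656) and red blood cells (0.625). Of 25 counts above 0 in this contrast, 16 moved by more than 1.5 times without some array, 0 of them counts above 5.

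The SP3 response of Experienced mice showed what serotype 3 does after past pneumonia. Cxcl3 rose by 6.59 (SE 0.61, n = 4, adjusted p 5.26e-06) and Hamp by 6.06 (SE 0.57, adjusted p 6.07e-06). Cxcl1 rose from 4.29 ± 0.13 in Experienced Control to 8.02 ± 0.22 in Experienced SP3, a change of 3.74 (SE 0.12, adjusted p 1.78e-11). Ifnb1, which encodes interferon beta, rose from 1.78 ± 0.40 to 6.16 ± 1.02 (adjusted p 1.13e-05). The sizes for Hamp, which averaged 1.62 in Experienced Control, and for Ifnb1 are not exact at such dim levels. The interferon-stimulated gene Ifit1 rose by 4.65 (SE 0.48, adjusted p 1.94e-05). P2ry6, a nucleotide receptor, fell by 1.71 (SE 0.19, adjusted p 3.63e-05) and Cnr2, a cannabinoid receptor, by 1.75 (SE 0.15, adjusted p 2.67e-06).

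Calls in Experienced mice came to 1662 genes, 728 risen and 934 fallen, 314 and 164 of them at least 2-fold. Unadjusted p-values lay below 0.05 for 4425 genes, or 17.6%. Without Experienced SP3 3 there were 1078 called genes, 570 of them fallen, and fallen genes numbered 613 without Experienced SP3 4 and 1402 without Experienced Control 3. Array weights called 3853 genes, 1548 risen and 2305 fallen, and the compared groups alone 1023, 476 and 547. Il23a (4.31), Cxcl10 (4.30), Acod1 (4.22), Ccl4 (4.11) and Serpina3f (3.93) were among the 10 largest increases. Gbp8 (-1.99), Adamts10 (-1.87), Tifab (-1.80), Igkv4-80 (-1.77), Iqce (-1.74), Dna2 (-1.67), Nlrp1b (-1.66) and Tmem273 (-1.66) joined Cnr2 and P2ry6 among the largest decreases.

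**Figure D2:**
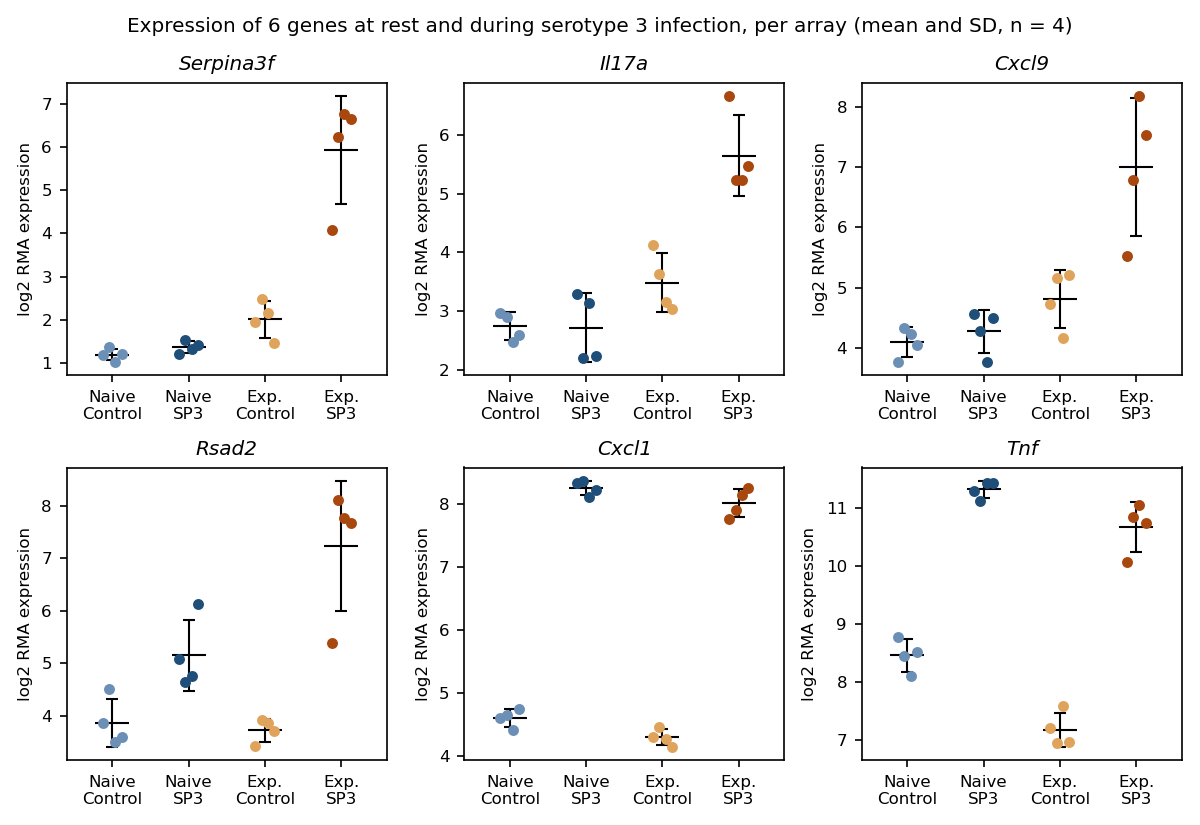
Log2 RMA expression (vertical axis) of Serpina3f, Il17a, Cxcl9, Rsad2, Cxcl1 and Tnf in the 4 groups (horizontal axis), with a dot per array, a line at the mean and bars of 1 SD, n = 4. Cxcl1 reached 8.26 in Naive SP3 and 8.02 in Experienced SP3, while Serpina3f averaged 1.37 and 5.94.

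Both interferon lists passed in Experienced mice. All 25 type I interferon-stimulated genes had a positive fold change and 10 rose, or 14 adjusted over the list alone, with a median of 0.82 (adjusted p 0.0146, adjusted p = 0.289 with an estimated correlation). Rsad2 rose by 3.52 (SE 0.46, adjusted p 0.000184) and Oasl1 by 3.50 (SE 0.51). The list lost its call without Experienced Control 4 (adjusted p 0.0513), Experienced SP3 3 (0.0608) and Experienced SP3 4 (0.0649), in a range of 1.05e-14 to 0.289, and 18 members rose without Experienced SP3 1. Of the interferon-gamma-inducible genes 8 rose and 0 fell, or 13 adjusted over the list alone, among them Irf1 (1.99), Gbp5 (2.50) and Cxcl9 (2.19, SE 0.40), with a median of 0.74 (adjusted p 0.00784, adjusted p = 0.289 with an estimated correlation). The number risen was 5 without Experienced SP3 2, 3 or 4. NF-kB regulators had 18 risen of 20, or 20 adjusted over the list alone, with Bcl3 (2.22) and Nfkbie (1.97) among them (median 1.34, adjusted p 2.43e-08, adjusted p = 0.000504 with an estimated correlation). Cytokines and chemokines had 17 risen of 29, or 21 adjusted over the list alone, with Tnf (3.51, SE 0.20) and Il1a (2.83, SE 0.20) among them (median 1.85, adjusted p 2.52e-07, adjusted p = 0.00267 with an estimated correlation). Camera called 7 lists with the preset correlation and 2 with an estimated correlation, and the mixed test called 13.

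The other lists missed in Experienced mice. Pattern recognition genes had 9 risen and 3 fallen of 29, or 13 and 4 adjusted over the list alone (median 0.36, adjusted p 0.0676), with Clec4e (2.71, SE 0.30) and Nod2 (1.04) among those that rose. The alveolar macrophage list had 7 risen and 4 fallen genes of 28, or 10 and 4 adjusted over the list alone (adjusted p 0.912), Fabp4 (2.39, SE 0.38) rising and Kcnn3 (-1.34, SE 0.12) falling. Hk2 (1.38) and Slc2a1 (1.12) rose again among 3 glycolysis genes (adjusted p 0.37). Ccl17 rose by 3.52 (SE 0.46) alone in the alternative activation list (adjusted p 0.0801), Vcan by 1.03 alone among the monocyte genes (adjusted p 0.976) and Ear6 by 2.24 alone among the eosinophil genes (adjusted p 0.381). Hypoxia genes had 3 risen members (adjusted p 0.912) and immediate-early and heat-shock genes 3 risen and 2 fallen (adjusted p 0.912), and as many passed adjusted over the list alone. No member was called in the lists of MHC class II, cholesterol synthesis, cell division, T cells and NK cells (adjusted p 0.976 for all 5), neutrophils (0.258), B cells (0.969), epithelium (0.986), fibroblasts and red blood cells (0.912 for both). Median, mean and test differed in sign for MHC class II, cholesterol synthesis, cell division, hypoxia and monocyte genes. Among 12 endothelial genes 2 fell, Tek by 1.49 (adjusted p of the list 0.228). Of 24 counts above 0 in this contrast, 15 moved by more than 1.5 times without some array, 4 of them counts above 5.

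The last question was whether the response to serotype 3 itself depended on history, which the interaction tests. No gene passed, 0 of 25206 by limma, with 941 genes (3.73%) at an unadjusted p below 0.05 and a smallest adjusted p of 0.0628. In simulated arrays with independent noise, 32% of 2-fold and 87% of 4-fold interactions among 25206 genes were recovered. The changed genes all had a mean level above the median of all values, so these shares do not cover dimmer genes. The 10 smallest p-values under the naming rule belonged to Serpina3f, whose SP3 response was 3.75 higher in Experienced mice (SE 0.58, adjusted p 0.0704), Igkv4-80 (-1.70, adjusted p 0.0704), Il17f (2.41, SE 0.44, adjusted p 0.264), Mkx (1.51, adjusted p 0.264), Il17a (2.18, SE 0.46, adjusted p 0.868), Prh1 (-0.95), Catspere1 (-0.88), Il2ra (1.33, SE 0.30), Zdhhc18 (0.89, adjusted p 0.868 for these 4) and Pdgfa (1.05, adjusted p 0.978), none of which passed. The type I interferon list had a median of 0.93 (fry p 0.0408, adjusted p 0.592) and the interferon-gamma list one of 0.63 (fry p 0.0403, adjusted p 0.592). No list passed by fry or by camera with an estimated correlation, and 17 did with the preset correlation. The 29 lists had 0 called members, while 1 NF-kB regulator and 1 neutrophil gene rose adjusted over the list alone, and the NF-kB and fibroblast lists had medians and means of opposite sign. Calls that passed in 1 history and missed in the other, such as those of the interferon lists, are therefore not shown to differ between the histories.

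Alternatives moved single interaction results across the threshold. The smallest adjusted p, 0.0628, belonged to AI839979 (1.90), a locus that the naming rule left out. It passed with the filter on dim probe sets (adjusted p 0.0470), quantile normalization (0.0473), the trend (0.0491) and array weights (0.00420). It also passed without Naive Control 3 (0.0380) and without Experienced SP3 1 (0.00113). Without Experienced SP3 1, 8 genes passed, including Serpina3f (4.37, adjusted p 9.04e-07), and both interferon lists did. Over all alternatives the adjusted p of Serpina3f ranged from 9.04e-07 to 0.231. Without Naive Control 3, Experienced Control 1 and Experienced SP3 2, 1 gene each passed, among them Igkv4-80 without Experienced Control 1 (adjusted p 0.0290, range 0.0290 to 0.231) and Il17f without Experienced SP3 2 (adjusted p 0.0339, range 0.0339 to 0.798).

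Responses of the 2 histories were set side by side in pairs of contrasts that shared no array. Of the genes called for SP3, 448 rose in both Naive and Experienced mice, against 22.2 expected for independent lists, and 665 fell in both, against 44.3. The latter numbered 438 without Experienced SP3 3. The number called in opposite directions was 0. Across all genes, which are not independent replicates, fold changes correlated with a Pearson r of 0.724 and a Spearman rho of 0.545, and across the 2513 genes called in either with 0.898 and 0.856. Experience effects at rest and during infection shared 31 higher genes, against 0.164 expected, and 55 lower genes, against 0.353, with 0 in opposite directions. Without Naive Control 4, Experienced Control 2 or Experienced SP3 2 the shared higher genes numbered 20 each, and without Experienced Control 3 they numbered 47. Their fold changes correlated with r of 0.451 and rho of 0.183 across all genes and with 0.864 and 0.871 across the 237 called in either. In both pairs the genes called in either were picked for their changes in the same contrasts, which raises these correlations. Genes lower in both states included Lepr, Pdk4, Adgrl3, Sema3e, Erc2, Epcam and Colec12, and those higher in both included Sash1, Msr1 and Cd93. These 2 pairs were the relations computed.

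**Figure D3:**
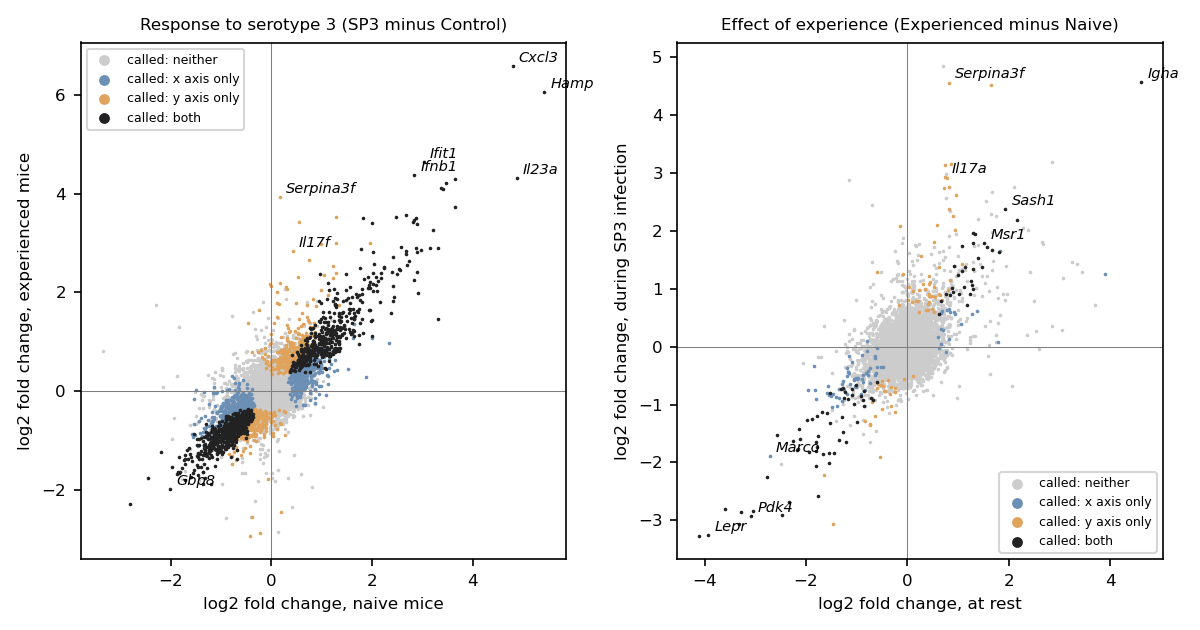
Log2 fold changes of all genes, with a point per gene coloured by the contrasts in which it was called. The left panel sets SP3 minus Control in Naive mice (horizontal axis) against Experienced mice (vertical axis), r = 0.724, and the right panel sets Experienced minus Naive at rest (horizontal axis) against infection (vertical axis), r = 0.451.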

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

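The tests for a compressed signal range and for exchanged labels on Experienced Control 3 were chosen after the result was seen. The test of a slope against surfactant genes and the regrouping without Experienced Control 3 were added after a first result on the same pattern. The bound for monocyte-derived macrophages was made stricter after its value was seen. An array stands out below where its gap to the nearest array of its group was too large a part of the range of the group for 4 samples, which chance gives in about 1 in 20 groups.

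Among 272 groups of values of named genes, 23 had such an array, against 13.6 by chance, and among 116 groups of list means there were 8, against 5.8. Properties of whole arrays gave 3, against 0.8. Experienced Control 3 had 8 of them, Naive SP3 1 and Experienced SP3 1 had 5 each and Experienced Control 4 had 4.

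Experienced SP3 1 lay apart from the other 3 arrays of its group in some values. On the first principal component, where every SP3 array lay above every Control array, it scored 6.96 against 24.9 to 35.7 in its group. That gap was not among those flagged. Its mean over type I interferon-stimulated genes was 4.13 against 5.40 to 5.58. Hamp stood at 5.40 against 8.27 to 8.62, Ccl4 at 7.20 against 8.86 to 8.90 and Fmnl2 at 4.12 against 6.04 to 6.16, while Il17a stood at 6.66 against 5.23 to 5.47. In Naive SP3 1, H2-Ab1 was 10.82 against 9.98 to 10.07, Cd74 was 11.23 against 10.51 to 10.56 and Fmnl2 was 3.61 against 2.28 to 2.50. Its list means were 2.18 against 1.85 to 1.88 for NK cells and 4.04 against 3.51 to 3.59 for endothelium.

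In Experienced Control 4, Vstm2a was 4.09 against 2.81 to 3.01, Ereg 3.87 against 3.37 to 3.43, Tlr5 5.54 against 4.99 to 5.06 and Pdgfa 3.63 against 3.01 to 3.06. Naive SP3 2 had Igha at 5.44 against 3.30 to 3.64, Lepr at 7.81 against 7.22 to 7.31 and Ifnb1 at 3.09 against 4.74 to 4.93. Naive Control 4 had Hamp at 1.91 against 2.23 to 2.30 and Acod1 at 4.84 against 3.36 to 3.41. Naive Control 1 had a cell division mean of 5.36 against 5.15 to 5.17, Naive Control 2 had Il23a at 2.99 against 1.90 to 2.06, and Naive Control 3 had Cxcl10 at 3.39 against 4.79 to 5.07. Further single values were those of Ighj3 in Experienced SP3 4 (7.03 against 8.05 to 8.25), Il17f in Experienced Control 2 (4.05 against 3.25 to 3.32), Tifab in Naive SP3 3 (3.42 against 4.13 to 4.22) and Zdhhc18 in Experienced Control 1 (5.76 against 5.91 to 5.94). No explanation was tested for these single values.

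Experienced Control 3 stood apart as an array. Its median was 2.82 against 2.55 to 2.56 in its group, its SD 2.00 against 2.22 to 2.24 and its mean correlation with its group 0.962 against 0.980 to 0.981. Its list means were 6.07 against 6.65 to 6.76 for pattern recognition, 5.16 against 6.03 to 6.19 for oxidative phosphorylation, 6.11 against 7.07 to 7.10 for the tricarboxylic acid cycle and 5.86 against 6.71 to 6.78 for fatty acid oxidation. Dna2 was 6.69 against 5.79 to 5.88.

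A compressed signal range, from the quality or amount of its RNA, is a candidate explanation for this array. Its deviation from the other 3 arrays of its group fell with their mean level (r = -0.489 across probe sets, against -0.240 to 0.151 on the other 15 arrays). A smaller SD by itself brings such a correlation, so it restates the values that set the array apart. RNA quality and amount were not measured here. An exchange of labels with Naive Control 3 was argued against, since its score over the genes that differed during infection lay 1.80 above the highest of the other Naive Control arrays, among the other Experienced Control arrays. Cells of another type stayed open, because the largest excess of another type's list, 0.607 for fibroblasts, fell between the bounds set for the test. Of 12 such lists 8 exceeded the other 3 arrays, with 0.578 for monocyte-derived macrophages. Compression also raises dim genes, so the 2 cannot be told apart by dim lists. The monocyte-derived macrophage list was not dim, with a mean of 5.34 on this array against at most 4.77 on the others of its group. A mean can still mix dim and bright members. Immediate-early and heat-shock genes, a bright list, rose there too (7.96 against 7.05 to 7.51), which compression alone does not account for. The design gives no biological explanation for 1 array.

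A set of 55 genes was lower in Experienced mice both at rest (median -1.66) and during infection (median -1.53). Lung epithelial cells with surfactant transcripts in the Naive samples were argued against by a slope of -0.00271 (95% interval -0.0934 to 0.0880) of the mean of these genes on that of Sftpc, Sftpa1 and Sftpb within groups, where carried cells need about 1, although the mean of Sftpc, Sftpa1, Sftpb and Scgb1a1 was itself lower at rest (-0.818, SE 0.795). That value passed the -0.5 set for such cells as the source, and Sftpc, which the opposite bound required not to fall, averaged 7.79 in Naive Control and 6.91 in Experienced Control (adjusted p 0.933). The mean of the 4 genes therefore excludes nothing by itself, since its wide error alone met the rest of that bound. In Naive Control the other 3 averaged 5.70, 6.15 and 7.54. The sort for CD11c and SiglecF is meant to remove such cells. How fully it did so is not known, since the mean of Sftpc, Sftpa1 and Sftpb spanned 4.97 among the 8 Naive arrays. Experienced Control 3 was not the source, since 92.7% of the genes were called at rest without it. Monocyte-derived macrophages in the gate cannot be told apart from a change in resident cells, because the mean of their list differed by -0.0193 (SE 0.329) at rest and -0.120 during infection, below 0 by less than the error, so a lasting change of the resident cells remains a hypothesis.

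Il17a and Il17f were higher in every Experienced SP3 array (5.23 to 6.66 and 5.29 to 7.38) than in every Naive SP3 array (2.20 to 3.30 and 2.97 to 3.38). A single array was not the source, since the highest adjusted p of either gene without any 1 array was 0.000789. T cells carried through the sort cannot be told apart from expression by macrophages, because the mean of the T cell list was 0.374 higher (SE 0.424, fry p 0.417), a difference too uncertain to decide. The sort for CD11c and SiglecF is meant to remove T cells, but how fully it did so is not known. Ctla4 (2.25) and Il2ra (1.25, chosen after its value was seen), also known from T cells, rose too. A rise in the macrophages themselves is thus open as well and was not tested.

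Other groupings of the same arrays were refitted for each count of called genes. Chance was argued against, though not excluded, for experience during infection, with 162 called genes against at most 48 in the other groupings. The same held for SP3 in Naive mice, with 1964 against at most 185, and in Experienced mice, with 1662 against at most 558. In each of these, 1 of 35 groupings (2.86%), the real one, called as many genes. That is the smallest share possible, and no correction was made for several comparisons. For experience at rest the groupings did not argue against chance, since 2 of 35 called as many, the real one with 161 and another with 801. Of the genes called at rest, 31 higher and 55 lower ones were called in the same direction during infection, on other arrays, with 0 in opposite directions. For independent lists 0.164 and 0.353 were expected, but genes are not independent and both contrasts shared 1 estimate of the spread. The overlap therefore shows a repeated direction and does not by itself exclude chance. The score over the genes that differed during infection, which were called on other arrays, was 1.21 to 1.65 in Experienced Control. In Naive Control it was -1.03 to -0.577. That separation argues against chance for these genes as a set, though not for each gene called at rest. This use of the score came after its values were seen. The grouping with 801 genes joined Experienced Control 3 with Naive Control 1, 2 and 4 and points to a structure of the samples that sets Naive Control 3 apart. The means of 9 of the 29 lists followed this grouping without overlap between its sides. On the side of Experienced Control 3 they were higher for dendritic cells (4.57 to 5.42 against 4.09 to 4.39), monocyte-derived macrophages (4.89 to 5.34 against 3.95 to 4.77), fibroblasts (3.47 to 4.25 against 3.00 to 3.39), immediate-early and heat-shock genes (7.84 to 8.11 against 6.93 to 7.51) and alternative activation (5.04 to 5.53 against 4.75 to 4.94). They were lower for glycolysis (5.17 to 5.49 against 5.64 to 5.87), oxidative phosphorylation (5.16 to 5.91 against 6.03 to 6.19), the tricarboxylic acid cycle (6.11 to 6.89 against 7.07 to 7.13) and fatty acid oxidation (5.86 to 6.60 against 6.71 to 6.88). The other 20 lists overlapped. These means were compared after the grouping was seen, and neither other cells nor the handling of the samples was tested as its origin. Without Experienced Control 3 again 2 of 35 groupings called as many, with 205 genes for the real one and 318 for the one that set Naive Control 1, 2 and 4 apart. For the interaction the real grouping called 0 genes, a number that each of 100 draws must reach, so the draws decide nothing, and the highest other called 381.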

How the results depend on the processing

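All alternatives were planned. None of the 196 called results of named genes, or 194 with the filter on dim probe sets, and none of the 8 list calls changed direction under any of them. Other called genes were not followed in this way. Over the 16 arrays left out in turn, called genes ranged from 106 to 205 for experience at rest, from 98 to 234 during infection, from 1209 to 2974 for SP3 in Naive mice, from 1078 to 2232 in Experienced mice and from 0 to 8 for the interaction. The lows came without Naive Control 4, Experienced SP3 2, Naive SP3 3 and Experienced SP3 3, and the highs without Experienced Control 3, except that the 8 came without Experienced SP3 1. The interaction also reached 1 without Naive Control 3, Experienced Control 1 and Experienced SP3 2, and experience during infection fell to 100 without Naive SP3 3 and without Experienced SP3 4.

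Array weights gave 358 genes at rest against 161, 322 during infection against 162, 3853 for SP3 in Experienced mice against 1662, and 2 for the interaction against 0. The fit of the compared groups alone, with fewer arrays to estimate the spread, gave 96 at rest and 1023 for SP3 in Experienced mice. It gave 2155 against 1964 for SP3 in Naive mice, so fewer arrays alone do not account for the falls. The filter on dim probe sets gave 2 interaction genes, with fewer genes tested, and quantile normalization and the trend with robust hyperparameters gave 1 each. The causes of these shifts were not tested. Remaining totals of called genes stayed within 1.5 times. Of 196 called named-gene results, quantile normalization lost 7, centring 18, the compared groups alone 29, the trend 7 and array weights 1, while the filter lost 0 of 194 and single arrays lost 7 to 23. Msr1, Cd36 and Krt19 at rest and Oas1g during infection missed with the compared groups alone (adjusted p 0.0620, 0.0805, 0.0686 and 0.0939, each the highest of its range).

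Lists called at rest numbered 0, and 7 with the preset correlation. Left-out arrays gave 0 to 2, with 2 without Naive Control 3 and 1 each without Naive SP3 1, Naive SP3 3, Experienced Control 3 and Experienced Control 4. During infection the 1 list became 0 with the compared groups alone and with an estimated correlation, 2 with array weights and 4 with the preset correlation. Left-out arrays gave 0 to 2, with 2 without Experienced SP3 1. For SP3 in Naive mice the 3 lists became 5 with quantile normalization, 6 with array weights and 7 with the preset correlation. Left-out arrays gave 2 to 6, with 6 without Experienced Control 3 and 5 without Naive Control 3. For SP3 in Experienced mice the 4 became 7 with the preset and 2 with an estimated correlation. Over all contrasts the fit of the compared groups alone lost 4 of the 8 list calls and added 2 others. The interaction had 17 with the preset correlation and 0 to 2 over left-out arrays, 2 being without Experienced SP3 1.

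The replicate numbers do not pair the arrays. Of 24 same-numbered pairs 6 correlated above 0.1 and 7 negatively, from -0.497 to 0.295, and 7 had their best partner under the same number. The replicate block gave 144, 142, 1866, 1548 and 0 called genes in the 5 contrasts. It gave 1 list at rest against 0, 0 during infection against 1, and lost 16 of the 196 named-gene results.

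Shared SP3 genes that fell ranged from 438 (without Experienced SP3 3) to 990 (without Experienced Control 3) and shared higher experience genes from 20 (without Naive Control 4, Experienced Control 2 or Experienced SP3 2) to 47 (without Experienced Control 3). The SP3 correlations became 0.795 (Pearson) and 0.729 (Spearman) without dim probe sets and ranged from 0.678 to 0.733 and 0.487 to 0.586 over left-out arrays. Those of experience became 0.548 and 0.303 and ranged from 0.375 to 0.483 and 0.129 to 0.274. Whether dim probe sets lie near the background is not known, since the deposited values do not give its level.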

Other observations

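The genes of this part were chosen after their values were seen, and no test followed. Cldn1, which encodes a tight junction protein, fell by 1.94 at rest (SE 0.20, adjusted p 3.86e-05) and by 1.81 during infection (SE 0.20, adjusted p 8.6e-05). Ocln, another tight junction gene, fell by 1.21 (SE 0.17) and 1.65 (SE 0.17), and Jup, which encodes plakoglobin, by 0.86 (SE 0.14) and 0.77 (SE 0.14). Scd1, a fatty acid desaturase, fell by 1.79 at rest (SE 0.30, adjusted p 0.00465) and by 1.73 during infection (SE 0.30, adjusted p 0.00729). Elovl6, a fatty acid elongase, fell by 1.96 at rest (SE 0.25, adjusted p 0.000307) and missed during infection (adjusted p 0.354). Esr1, the estrogen receptor, rose by 1.26 at rest and 1.14 during infection (SE 0.20 for both), and Timp2, a protease inhibitor, by 0.88 and 1.02. Of these results only the calls of Ocln and Scd1 at rest were lost under an alternative, the fit of the compared groups alone (adjusted p 0.0522 and 0.0922, in ranges of 0.0004 to 0.0522 and 0.00143 to 0.0922).

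Infection moved further genes in both histories. Slc11a2, an iron importer, rose by 1.97 in Naive and 1.63 in Experienced mice (SE 0.24 for both), beside Hamp. Ptges, which makes prostaglandin E2, rose by 2.90 and 2.42, and Ch25h, which makes an oxysterol, by 2.90 and 2.83. Inhba, a subunit of activin A, rose by 2.97 and 2.85. Pparg, a regulator of alveolar macrophage identity, fell by 0.76 (SE 0.15, adjusted p 0.00385) and by 0.77 (SE 0.15, adjusted p 0.00393). These calls held under every alternative.

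Jchain, Igkc, Ighm, Mzb1 and Sdc1, known from plasma cells and B cells, did not pass. Jchain averaged 3.40 in Naive Control and 6.25 in Experienced Control (adjusted p 0.357, range 0.0209 to 0.763), Igkc 8.66 and 10.34 (adjusted p 0.73, range 0.273 to 1) and Ighm 7.96 and 9.36 (adjusted p 0.861), while Mzb1 averaged 2.41 and 2.62 and Sdc1 3.72 and 3.68. During infection the fold changes were 3.19 for Jchain (adjusted p 0.208, range 0.0128 to 0.564) and 1.98 for Igkc (adjusted p 0.545, range 0.0351 to 0.895). Jchain thus passed in both states and Igkc during infection under at least 1 alternative. No explanation was tested for the immunoglobulin transcripts.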
